A study of Arabidopsis thaliana with 3 samples.

How the data were processed

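RNA sequencing was carried out on 3 pools of dissected Arabidopsis thaliana inflorescence meristems of the accession Col-0, the common laboratory wild type. Per the labels' protocols, plants grew for 4 weeks in short days of 8 h light and then for 2 weeks in long days of 16 h light. Each pool held 10 inflorescences, from which flower buds had been taken off up to the primordium stage called P5, and the tissue was frozen in liquid nitrogen within 3 min. RNA came from the PicoPure kit, libraries were made with a strand-specific TruSeq protocol, and paired reads of 100 bp were taken on a HiSeq2000.

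The deposited values are raw counts per gene, 1 whole number for each of 32678 Arabidopsis loci in each library, with no normalisation. The submitters' processing notes name the genome build TAIR10, FastQC, Bowtie2 2.2.5, TopHat2 2.1.0 and HTSeq 0.6.1. The role of each tool, the strand setting of the counting, the annotation release and the rule for reads that fall on several places are not given in the sources used here. Each of these settings can move the count of a gene that has a near-identical copy or that overlaps another gene. No line without a gene name was present (0 in each library). Total counts assigned to genes were 29094404, 28948463 and 27254114 in replicates 1, 2 and 3.

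Locus identifiers were matched to the RefSeq annotation of the assembly TAIR10.1, which gave symbols, descriptions, gene types, exon lengths and coordinates. Of the 32678 loci, 31912 matched. The 133 chloroplast and 146 mitochondrial loci were left out of library sizes and tests. CPM values (counts scaled by library size) were computed on the nuclear counts of each library. A length-normalised level, here called TPM-like, divided CPM by the union of a gene's exons and was scaled to the same total in each library. A nuclear protein-coding gene was counted as expressed at 1 CPM or more in each of the 3 libraries, which is about 29.1, 28.9 and 27.2 counts in replicates 1, 2 and 3. A count of 0 allows a level of up to 0.103, 0.104 and 0.110 CPM (3 counts). Sequencing reads without molecular identifiers are not independent molecules, so these floors cover counting error only.

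All libraries belong to 1 group, and the replicate numbers come from the sample titles, so no comparison between groups was possible. The labels do not say whether the 3 pools were grown or dissected apart, and p-values over the libraries then measure only the spread between these pools, which may be technical. The lists of genes, the families, the contrasts, the tests and the alternatives were fixed before the data were examined, apart from those said to be chosen or added after the data were seen. Of 410 members of 27 gene lists, 406 entered because the reference gave the identifier the listed name as symbol or synonym. KRP4, E2FA, A9 and TIP41 were left out. The share of each list's members that was expressed was set against all other nuclear protein-coding genes with a two-sided Fisher exact test, adjusted by Benjamini-Hochberg over the 27 lists. The 17 gene families, matched on the reference descriptions, were treated in the same way. Genes of a list are not independent replicates, so these tests place a list among the genes of these libraries. As a description, the median TPM-like level of a list was also placed among those of 10000 random lists of equal size.

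For 16 contrasts between genes or groups of genes, the log2 ratio of summed TPM-like levels was taken within each library, and its mean over the 3 libraries was tested against 0 with limma (two-sided, intercept only, Benjamini-Hochberg over the 16). An exact sign-flip test with 3 libraries cannot give a p below 0.25. Spread between libraries was estimated with edgeR (TMM factors of 1.00, 1.02 and 0.978, intercept-only design) as a biological coefficient of variation over the 18334 nuclear genes kept by filterByExpr, of which 17886 are protein-coding. Genes that varied more than the dispersion trend were called by edgeR's goodness-of-fit statistic (chi-square with 2 degrees of freedom, Benjamini-Hochberg, threshold 0.05), and a second fit used Poisson variation alone.

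Genes are named by a rule. It takes up to 4 members of each list with the highest TPM-like level and up to 3 of the lowest below 1 CPM. It takes WUS, CLV3, STM, LFY, AP1, TFL1, ARF5, AHP6 and CUC2 in any case, and both members of contrasts between 2 genes. It adds the 20 protein-coding genes with the highest TPM-like level and the 10 highest genes described as a transcription factor. It also adds the 10 varying genes with the largest ratio of highest to lowest CPM and a mean of at least 10 CPM. Some genes and a ratio that the rule or the contrasts take in are not reported here. A gene named outside this rule is said to be chosen after its values were seen.

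Each step was tested on simulated data. Over 18334 simulated genes, the goodness-of-fit step recovered 37 of 100 genes with a planted 2-fold change in 1 library and 99 of 100 with a 4-fold change, with 9 false calls, and it called 0 genes when none was planted. Changes were planted only in genes with a mean of at least 100 counts, so the recovery does not cover genes with fewer counts. All simulated genes were drawn with the dispersion of the trend itself. The false calls therefore do not cover genes whose own dispersion lies off the trend. The limma step on 1000 simulated ratios recovered 200 of 200 planted shifts of 1 log2 unit with 8 false calls. These simulated ratios were drawn with an SD of 0.15. The SDs of the fixed contrasts ran from 0.026 for AP1 over CAL to 0.51 for primary over secondary wall cellulose synthases. The recovery and false calls therefore do not cover contrasts with a larger SD, or a fit with far fewer ratios. The list test called 0 of 500 random lists of 20 genes and recovered 100 of 100 planted lists. Each planted list held 20 expressed genes and no other, so all gave the same result. Their recovery says nothing about smaller lists or lists expressed in part. Alternatives covered the level that counts as expressed, the unit, the normalisation, the low-count filter, the dispersion, the gene length and leaving out each library. A filter on a mean of at least 10 counts was added after seeing the data, because filterByExpr asks for counts in all 3 libraries and so drops genes that are high in 1 library. A ratio of mean levels per gene in place of summed levels was also added after seeing the data, because several contrasts set unequal numbers of genes against each other. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 (size factors and a dispersion trend as alternatives), and Python 3.11.15 with SciPy 1.17.1, statsmodels 0.14.6, pandas 2.3.3 and matplotlib 3.10.9.

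Among the list members, 7 overlap another gene on the same strand and 79 overlap one on the opposite strand. Without the strand setting of the counting, reads of the latter cannot be assigned with certainty.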

Results

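The series measured which genes are expressed in the dissected inflorescence meristem of wild-type Arabidopsis, the dome of dividing cells at the tip of a flowering shoot that keeps its stem cells and makes flower primordia on its flanks. It holds 1 group of 3 libraries, each from a pool of 10 inflorescences. A level is an average over all cells of a pool, including any flower primordia left on it. Levels and ratios between genes therefore also depend on the share of cells that express each gene. Nuclear genes took 29078107, 28933042 and 27236559 counts in replicates 1, 2 and 3, and protein-coding genes held 99.3%, 99.3% and 99.4% of them. Values below are means ± SD of CPM over the 3 libraries unless stated otherwise, and coordinates are those of TAIR10.1.

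Of 26700 nuclear protein-coding genes, 16866 (63.2%) were expressed, 5122 had counts without reaching 1 CPM in each library, and 4712 were listed at 0 in all 3. Among the expressed genes, 12922 reached 10 CPM in every library, 1933 reached 100 CPM and 28 reached 1000 CPM. The highest TPM-like level belonged to CAB1 (AT1G29930, chromosome 1, 10477885 to 10479114), a chlorophyll a/b binding protein of the light-harvesting antenna, at 4758 ± 188 CPM (n = 3). CAB1 has near-identical neighbours in CAB2 and CAB3, and its split from them is uncertain. Further light-harvesting genes among the top 20 were LHB1B2, LHCA4 and LHCA1, and RBCS1A, a small subunit of Rubisco, stood at 3046 ± 315 CPM (n = 3). The rest of the 20 included the translation genes TCTP, AT5G60390, AT4G27090, emb2386, AT5G20290 and AT3G60245, the lipid transfer proteins LTP6 and LTP1 (listed in the reference as LP1), the metallothionein MT2B, the cysteine-rich LCR69 and the water channel PIP3. It also included VSP1 at 2257 ± 751 CPM, the beta glucosidase BGLU18 at 6041 ± 1985 CPM, SIP2 at 3627 ± 935 CPM and AT3G15450 at 3943 ± 1363 CPM (n = 3 each), whose SDs were the largest of the 20 relative to the mean. The genes CAB1, AT3G15450, LHB1B2, LHCA4 and AT5G60390 overlap a gene on the opposite strand.

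Genes that keep the meristem were expressed over a wide range. The class I KNOX gene STM (AT1G62360, chromosome 1, 23058582 to 23062063), needed to hold meristem cells undifferentiated, stood at 113 ± 14.1 CPM (n = 3), and its relatives KNAT1 and KNAT6 stood at 111 ± 34.7 and 75.0 ± 3.13 CPM. The highest member of the stem cell and meristem list was the receptor kinase BAM1 at 305 ± 25.4 CPM. The 2 genes of the stem cell feedback loop were low as averages over the pools, which does not say how strongly single cells express them. WUS (AT2G17950, chromosome 2, 7808871 to 7810811), which marks the organising centre, had 110, 96 and 129 counts, or 3.95 ± 0.723 CPM, and CLV3 (AT2G27250, chromosome 2, 11664978 to 11665797), which marks the stem cells, had 20, 26 and 30 counts, or 0.896 ± 0.207 CPM. CLV3 was therefore below the threshold in replicates 1 and 2, as were HEC1, HEC2 and HEC3 in at least 1 library. Of 23 members, 19 were expressed, against 63.2% of the other genes, which did not pass the Fisher exact test (adjusted p = 0.0917). At 0.5 CPM, with 95.7% of members counted, the list passed (adjusted p = 0.00481).

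Among the flowering and floral genes, AP1 (AT1G69120, chromosome 1, 25982294 to 25986349), a MADS-box gene of floral meristems and sepals and petals, stood at 263 ± 17.1 CPM (n = 3), and LFY (AT5G61850, chromosome 5, 24844248 to 24846989), the floral meristem regulator, at 88.7 ± 15.8 CPM. TFL1 (AT5G03840, chromosome 5, 1024500 to 1025872), which keeps the shoot tip from turning into a flower, stood at 6.70 ± 1.42 CPM. The floral organ genes PI and AP3 were at 115 ± 15.0 and 105 ± 6.90 CPM, and the organ growth gene ANT was at 239 ± 26.7 CPM. Of 20 floral identity genes 19 were expressed, above the share of the other genes (95% against 63.1%, Fisher exact test, adjusted p = 0.00724). The exception was PUCHI at 1.09 ± 0.382 CPM. At a threshold of 5 CPM the list no longer passed (80.0%, adjusted p = 0.0677). In the flowering list, the highest members by TPM-like level were SPL3 (339 ± 46.1 CPM), SPL4 (230 ± 3.70 CPM), FUL (94.4 ± 4.37 CPM) and SPL9 (95.4 ± 23.1 CPM), which act in the floral transition. FT, the flowering signal made in leaves, was listed at 0 in all 3 libraries, its relative TSF had 3, 4 and 4 counts, and the repressor FLC was at 0.709 ± 0.380 CPM. Of the 15 flowering genes, 12 were expressed (adjusted p = 0.364).

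**Figure D1:**
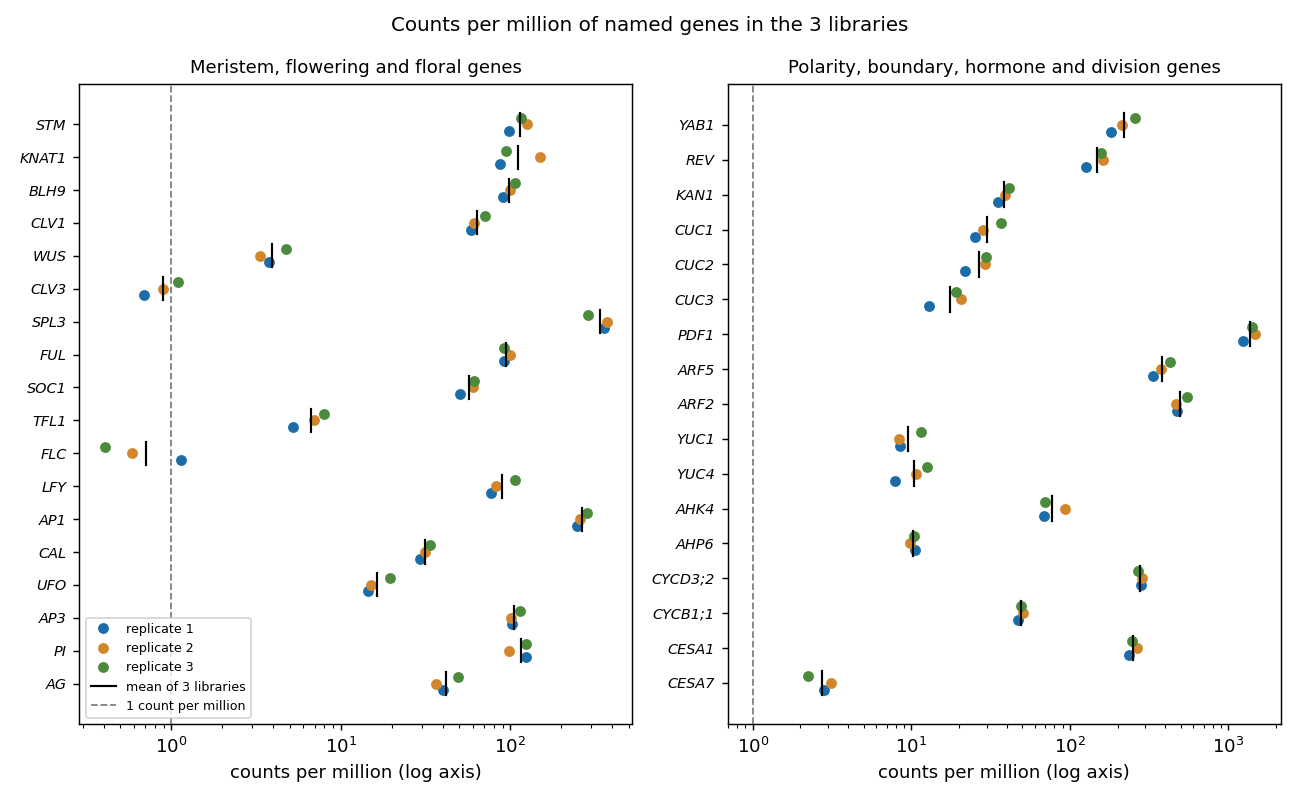
CPM of genes from the fixed lists (log axis), with 1 point per library, a black line at the mean of the 3 libraries and a dashed line at 1 CPM. The genes were picked for display after their values were seen, and STM near 113 CPM and AP1 near 263 CPM lie far above WUS at 3.95 CPM and CLV3 at 0.896 CPM.

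Genes of organ patterning were expressed without exception in 2 lists. All 17 adaxial-abaxial polarity genes (adjusted p = 0.00306) and all 11 organ boundary genes (adjusted p = 0.0255) passed 1 CPM in each library, although the boundary list lost its call at 5 CPM (72.7%, adjusted p = 0.394). YAB1 (listed as AFO in the reference), an abaxial gene of lateral organs, was at 218 ± 38.8 CPM (n = 3), AGO10 at 265 ± 27.5 CPM, AS1 at 147 ± 13.7 CPM and YAB3 at 85.2 ± 11.2 CPM. The boundary gene CUC2 (AT5G53950, chromosome 5, 21901704 to 21903854) was at 26.8 ± 4.35 CPM, next to LSH3 at 47.4 ± 5.70, LOF1 at 33.9 ± 5.93 and CUC1 at 30.0 ± 5.91 CPM. The epidermal list had 7 of 7 members expressed (adjusted p = 0.0917). Its highest TPM-like levels were those of LTP1 at 1206 ± 31.9 CPM, PDF1 at 1374 ± 125 CPM, FDH at 276 ± 13.9 CPM and the layer regulator PDF2 at 232 ± 5.07 CPM. Of 10 vascular genes 6 were expressed (adjusted p = 1), among them TMO6 at 85.5 ± 2.65 CPM, TMO5 at 46.7 ± 9.68 CPM, PXY at 50.9 ± 11.6 CPM and the phloem sugar carrier SUC2 at 17.8 ± 7.01 CPM. The xylem regulators VND6 and VND7 were at 0.58 ± 0.34 and 0.429 ± 0.237 CPM. LHW was listed at 0, and it lies next to a locus that the reference lacks.

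Auxin genes made up 5 lists, of which 1 passed against the other genes. All 11 auxin receptors and corepressors were expressed (adjusted p = 0.0255). Their highest TPM-like levels were those of TIR1 at 251 ± 24.1 CPM (n = 3), TPL at 314 ± 22.7 CPM, AFB5 at 175 ± 10.0 CPM and AFB1 at 124 ± 19.2 CPM. Of 22 auxin response factors 15 were expressed (adjusted p = 0.892), with ARF2 at 495 ± 45.2 CPM, ARF6 at 441 ± 42.4 CPM, ARF5 at 380 ± 46.7 CPM and ARF1 at 203 ± 4.39 CPM. ARF5 (AT1G19850, chromosome 1, 6886669 to 6891404), which is needed for flower initiation, overlaps a gene on the opposite strand. The other 7 factors, ARF12 to ARF15 and ARF20 to ARF22, form a cluster of near copies and were listed at 0, so that reads shared among them cannot be ruled out. Of 29 Aux/IAA repressors 20 were expressed (adjusted p = 0.668), with IAA8 at 405 ± 9.49, IAA9 at 321 ± 37.0, IAA4 at 64.3 ± 4.74 and IAA26 at 96.2 ± 7.38 CPM, while IAA6 and IAA15 were listed at 0 and IAA5 had 1 count. Among auxin transport genes, LAX2 was at 99.1 ± 16.0, the kinase PID at 100 ± 21.2 and LAX1 at 51.2 ± 0.609 CPM. Of 13 transport genes 11 were expressed (adjusted p = 0.204), and PIN5 and PIN8 were below the threshold. Auxin synthesis had 5 of 14 members expressed (35.7%, adjusted p = 0.0917), namely TAR2 at 42.9 ± 1.72, TAA1 at 21.2 ± 3.51, YUC1 at 9.49 ± 1.83, YUC4 at 10.4 ± 2.30 and, named after its value was seen, YUC6 at 2.99 ± 0.663 CPM. YUC5, YUC7, YUC9, YUC10 and YUC11 were listed at 0.

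Cytokinin signalling had 21 of 26 members expressed (adjusted p = 0.109) and cytokinin metabolism 12 of 18 (adjusted p = 1). The response regulator ARR7 was at 43.0 ± 11.5 CPM (n = 3), ARR1 at 105 ± 20.5 CPM, AHP2 at 30.2 ± 1.27 CPM and AHP3, which overlaps a gene on the same strand, at 29.9 ± 1.0 CPM. AHP6 (AT1G80100, chromosome 1, 30133718 to 30134937), an inhibitor of cytokinin signalling that acts in the timing of organ initiation, was at 10.3 ± 0.364 CPM. AHP4 was listed at 0, and ARR3 and ARR17 were at 0.0574 ± 0.0526 and 0.0698 ± 0.0593 CPM. Among metabolic genes LOG5 stood at 36.6 ± 3.42, CKX6 at 43.1 ± 6.92, LOG1 at 19.6 ± 3.29 and CKX7 at 23.4 ± 3.71 CPM, while IPT5 was listed at 0, and CKX2 and LOG2 were at 0.0122 ± 0.0212 and 0.0230 ± 0.0199 CPM. The gibberellin list had 11 of 13 members expressed (adjusted p = 0.204), with the DELLA repressor RGA at 126 ± 14.9, GAI at 59.6 ± 7.04, and the receptors GID1A at 63.7 ± 3.04 and GID1B at 51.3 ± 10.9 CPM. The synthesis genes GA20ox1 and GA3ox1 were at 1.51 ± 0.793 and 1.05 ± 0.274 CPM.

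Cell division genes had the lowest adjusted p of the 27 lists, with 35 of 36 expressed (97.2% against 63.1%, Fisher exact test, adjusted p = 5.6e-05). CYCD3;2 was at 279 ± 9.73 CPM (n = 3), the cytokinesis gene KN at 172 ± 3.01 CPM, CYCD3;3 at 136 ± 21.3 CPM and the mitotic kinase gene CDKB2;1 at 105 ± 7.17 CPM. The exception was the inhibitor gene KRP1 at 0.713 ± 0.161 CPM. All 18 chromatin and small RNA genes were expressed (adjusted p = 0.00228), led by AGO1 at 641 ± 67.4, AGO4 at 315 ± 33.5, the demethylase ROS1 at 181 ± 17 and the methyltransferase CMT3 at 98.0 ± 3.88 CPM. The 16 photosynthesis genes were all expressed as well (adjusted p = 0.00453), with LHCB5 at 1339 ± 76.2 and LHCB3 at 1173 ± 120 CPM after CAB1 and RBCS1A. All 10 clock genes passed (adjusted p = 0.0414), PRR7 being highest at 219 ± 17.2 CPM before TOC1 at 108 ± 9.89, ELF3 at 91.2 ± 3.41 and PRR5 at 62.1 ± 17.1 CPM. The clock list lost its call at 5 CPM (80.0%, adjusted p = 0.272) and at 10 counts (100%, adjusted p = 0.0583). Primary wall cellulose synthases stood at 256 ± 29.3 CPM for CESA3, 249 ± 14.0 for CESA1 and 138 ± 23.8 for CESA6, against 2.72 ± 0.443 for CESA7 and 2.03 ± 1.06 for CESA4, the latter overlapping a gene on the same strand, and 5 of 6 were expressed (adjusted p = 0.520). All 6 reference genes were expressed (adjusted p = 0.138), with GAPC1 at 692 ± 52.4, UBQ10 at 698 ± 96.6, TUB4 at 492 ± 42.6 and ACT2 at 311 ± 16.8 CPM.

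Genes of other organs served as background. None of 11 root genes was expressed (adjusted p = 0.000228), the highest being WOX5 at 0.434 ± 0.0191 CPM, followed by WER at 0.212 ± 0.0942 CPM, and 8 were listed at 0. None of 8 seed storage genes was expressed (adjusted p = 0.00228), SESA1 at 0.168 ± 0.142 and SESA3 at 0.110 ± 0.191 CPM being the highest. Of 4 pollen genes 0 passed in all libraries (Fisher exact test, adjusted p = 0.0414). This call ended without replicate 3 (25.0%, Fisher exact test, adjusted p = 0.192) and at 5 CPM (0%, Fisher exact test, adjusted p = 0.0851). VGD1, a pollen tube pectin methylesterase, had 2.58, 12.2 and 0.330 CPM in replicates 1, 2 and 3, and GRP14, PPME1 and GRP17 had means under 1 CPM. The ovule and carpel list had 4 of 7 members expressed (adjusted p = 0.803), with the carpel genes CRC at 45.1 ± 5.74, SPT at 51.1 ± 3.06, SHP2 at 2.71 ± 1.03 and SHP1 at 2.59 ± 0.0847 CPM (n = 3), while INO was listed at 0, and STK and BEL1 were at 0.126 ± 0.218 and 0.837 ± 0.457 CPM. The anther list had 4 of 12 expressed (adjusted p = 0.0809). EMS1, a receptor kinase gene of early anthers, was at 75.6 ± 21.9 CPM, and LAP6, a tapetum gene of pollen wall formation, was at 23.9 ± 1.41 CPM, even across the libraries. The tapetum genes AMS and ACOS5 were high in replicate 1 only, with 58.3, 0.380 and 0.0367 CPM for AMS and 46.2, 0.415 and 0.0734 CPM for ACOS5. MS1 and CYP703A2 were listed at 0, and MYB80 was at 0.229 ± 0.368 CPM. AMS overlaps a gene on the opposite strand.

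**Figure D2:**
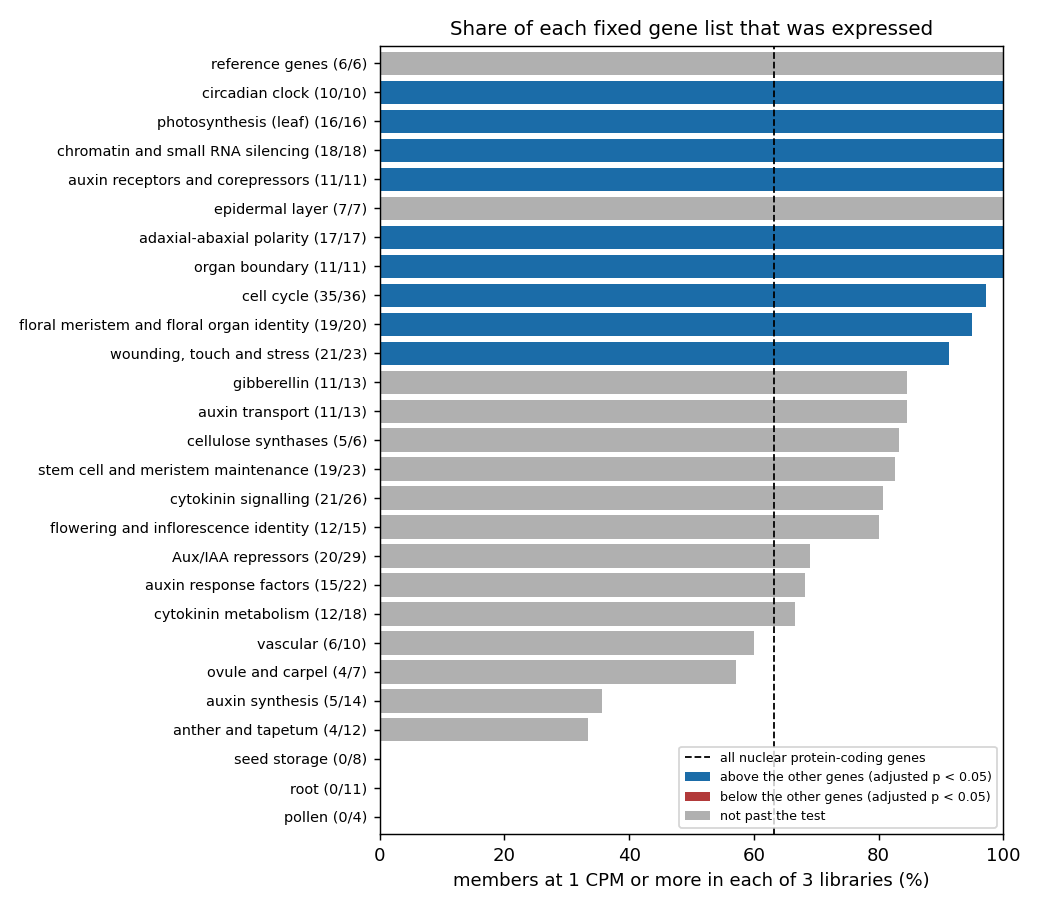
Share of the members of each of the 27 gene lists at 1 CPM or more in all 3 libraries (bars, %), with members expressed and members measured in brackets and the share of all nuclear protein-coding genes, 63.2%, as a dashed line. Blue bars passed the Fisher exact test above the other genes, grey bars passed in neither direction, and the pollen, root and seed storage lists, which passed below, have a share of 0.

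Gene families ranged from all members expressed to almost none. The largest shares above the other genes were those of tubulins (22 of 22), kinesins (27 of 29), ribosomal proteins (314 of 343), pentatricopeptide repeat proteins (252 of 278), chlorophyll a/b binding proteins (24 of 27) and histones (45 of 51). Homeobox genes (156 of 208, adjusted p = 0.000387) and heat shock genes (82 of 110, adjusted p = 0.0139) passed too. Ribosomal protein genes held 7.61 ± 0.232% of nuclear counts and histone genes 0.751 ± 0.00402% (n = 3). Below the other genes were defensin-like genes (2 of 113), peroxidases (15 of 75), F-box genes (149 of 629), lipid transfer genes (34 of 139), pectinesterases and pectin lyases (65 of 231), late embryogenesis abundant genes (24 of 85), MADS-box genes (37 of 118) and cytochromes P450 (90 of 248). The largest adjusted p among these 8 was 1.5e-10. Disease resistance genes did not differ in share at 1 CPM (116 of 191, Fisher exact test, adjusted p = 0.498), but passed below the others at 5 CPM (41.9%) and 1 TPM-like (55.5%). Their median TPM-like level, 1.78, exceeded only 0.01% of the random lists of equal size. For pentatricopeptide repeat genes, with a median of 4.89, that figure was 1.15%, so many were expressed at low levels. For the other families that passed above, it was 68.15% or more. At 5 CPM, homeobox, pentatricopeptide repeat and heat shock genes no longer passed (61.5%, 56.8% and 62.7% expressed). The 10 highest genes described as transcription factors were the linker histones AT1G06760 and AT2G30620, BTF3, YAB1, AP1, WLIM2b, HON4, GTE2, BZO2H3 and PI. Their levels ran from 484 ± 17.8 CPM for AT1G06760 to 115 ± 15.0 CPM for PI (n = 3), and HON4 overlaps a gene on the same strand.

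Of 16 fixed ratios between genes or groups of genes, 14 differed from 1 (limma, adjusted p under 0.05), each in the same direction in 3 of 3 libraries. Primary over secondary wall cellulose synthases gave the largest log2 ratio, 6.32 ± 0.51 (SD, n = 3, limma, adjusted p = 3.5e-06). PI and AP3 together exceeded AG, the stamen and carpel identity gene, by 3.13 ± 0.11, LFY exceeded TFL1 by 3.07 ± 0.16, AP1 exceeded its close relative CAL by 2.57 ± 0.03, and ANT exceeded AIL6 by 2.60 ± 0.13 log2 units. YUC1 with YUC4 exceeded the other 9 YUC genes by 2.66 ± 0.31, class III HD-ZIP genes exceeded KANADI genes by 2.13 ± 0.10, CUC1 with CUC2 exceeded CUC3 by 1.82 ± 0.21, and TIR1 exceeded AFB1 by 0.84 ± 0.36. The ratio of CLV3 to WUS was -1.54 ± 0.29, and that of the CYCB1 genes to the CYCD3 genes -1.18 ± 0.11. Ratios of sums depend on the number of genes on each side. As a mean level per gene, PI and AP3 over AG was 2.13, CUC1 and CUC2 over CUC3 0.82, YUC1 and YUC4 over the other YUC genes 4.83, class III HD-ZIP over KANADI genes 1.81 and CYCB1 over CYCD3 genes -1.59, an alternative chosen after seeing the data under which these 5 still passed. The receptor AHK4 against AHK2 and AHK3 together gave -1.07 ± 0.25, but -0.07 per gene (limma, adjusted p = 0.629), and the 5 activating against the 10 repressing ARF genes gave -0.56 ± 0.07 (-0.27 with no length correction), but 0.44 per gene (limma, adjusted p = 0.00625), so neither sum says which side is higher gene for gene. The largest adjusted p of the 14, for TIR1 over AFB1, was 0.00345 (limma). STM over KNAT1 (0.31 ± 0.29, limma, adjusted p = 0.0758, 2 of 3 libraries) did not pass, although it did without replicate 2 (0.48, limma, adjusted p = 0.0193). Type-A over type-B ARR genes (-0.44 ± 0.49, limma, adjusted p = 0.0758, 2 of 3 libraries) did not pass either, but did with no length correction (-1.28, limma, adjusted p = 0.00159) and per gene (-0.96, limma, adjusted p = 0.00565).

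The 3 libraries agreed closely for most genes and parted in specific ones. Across genes, which are not independent replicates, log2(CPM + 1) correlated with Pearson r of 0.985, 0.983 and 0.985 and Spearman rho of 0.986, 0.985 and 0.986 for replicates 1 and 2, 1 and 3, and 2 and 3. Counts of each pair differed by more than sampling noise (chi-square per degree of freedom of 37.3, 31.5 and 32.0), so no library was a copy of another. The biological coefficient of variation was 16.7%, and the median CV of expressed genes was 8.72%. Of 18334 genes, 462 varied more than the trend (edgeR goodness of fit, adjusted p under 0.05) and 11179 varied more than Poisson sampling. Without replicates 1, 2 and 3 in turn, 236, 289 and 216 genes varied. The library farthest from the other two was replicate 3, with the lowest level, in 146 of the 462 genes, and replicate 1, with the highest level, in 132; with the filter on the mean count described below the order was the other way round, 156 and 216 of 562.

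Among genes kept by filterByExpr, the varying genes with the largest ratio of highest to lowest level were led by the peroxidase gene AT1G44970 (61.1, 0.577 and 1.58 TMM-scaled CPM in replicates 1, 2 and 3). Behind it came RRTF1, AT2G27080, CML37, CBF1, WRKY46, AT4G29780, ACS6, AT5G64870 and BCS1. Each of these 9 was highest in replicate 1 and lowest in replicate 3, as RRTF1 with 61.5, 19.8 and 1.65 and ACS6, an ethylene synthesis gene, with 273, 103 and 20.5 TMM-scaled CPM. In the list of wounding, touch and stress genes, 21 of 23 members were expressed (91.3%, adjusted p = 0.0136). Of the 22 members tested, 15 varied more than the trend (17 when adjusted over the list alone). Of these 15, 12 were highest in replicate 1 and lowest in replicate 3, among them CBF1 (27.4, 7.40 and 0.991 CPM) and the touch gene TCH4 (259, 168 and 63.7 CPM). The jasmonate-responsive genes VSP2 (380, 794 and 965 CPM), LOX2 (145, 271 and 438 CPM) and, chosen after its values were seen, JAZ10 (11.6, 23.5 and 29.6 CPM) were lowest in replicate 1. VSP1, a near copy of VSP2, had 1393, 2756 and 2622 CPM and did not pass (edgeR, adjusted p = 0.132), and HSP17.4 had 1 count in all. Of 336 list members tested in all, 17 varied (24 when each list was adjusted alone), and the other 2 were AGO5 and RBCS2B, both named after their values were seen. In the meristem, floral, polarity, boundary and cell cycle lists 0 members varied (edgeR, with 1, 1, 0, 0 and 1 at an unadjusted p under 0.05, and 0 again with the filter on the mean count described next). The clock list had 0 of 10 (2 when adjusted over the list alone, 4 unadjusted), and cytokinin signalling had 0 of 23 (6 unadjusted). Since the step recovered only 37 of 100 simulated 2-fold changes, a count of 0 does not show that these genes were alike in the pools.

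With a filter on the mean count, added after seeing the data, 562 genes varied. The anther list then had 4 varying members of 8 tested, all highest in replicate 1. These were AMS (edgeR, adjusted p = 3.0e-80), ACOS5 (edgeR, adjusted p = 2.4e-64) and, named after their values were seen, LAP5 (6.57, 0.104 and 0.147 CPM) and TDF1 (2.2, 0.173 and 0.110 CPM). LAP5 overlaps a gene on the same strand. VGD1 varied as well (edgeR, adjusted p = 4.7e-08). With this filter, 10 varying genes with a mean of at least 10 CPM, AMS and ACOS5 among them, had a larger ratio of highest to lowest level than AT1G44970, all 10 highest in replicate 1. In all, 53 protein-coding genes with at least 100 counts were at least 10 times higher in replicate 1 than in both other libraries, against 0 for replicate 2 and 1 for replicate 3. They held 0.151% of the nuclear counts of replicate 1.

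**Figure D3:**
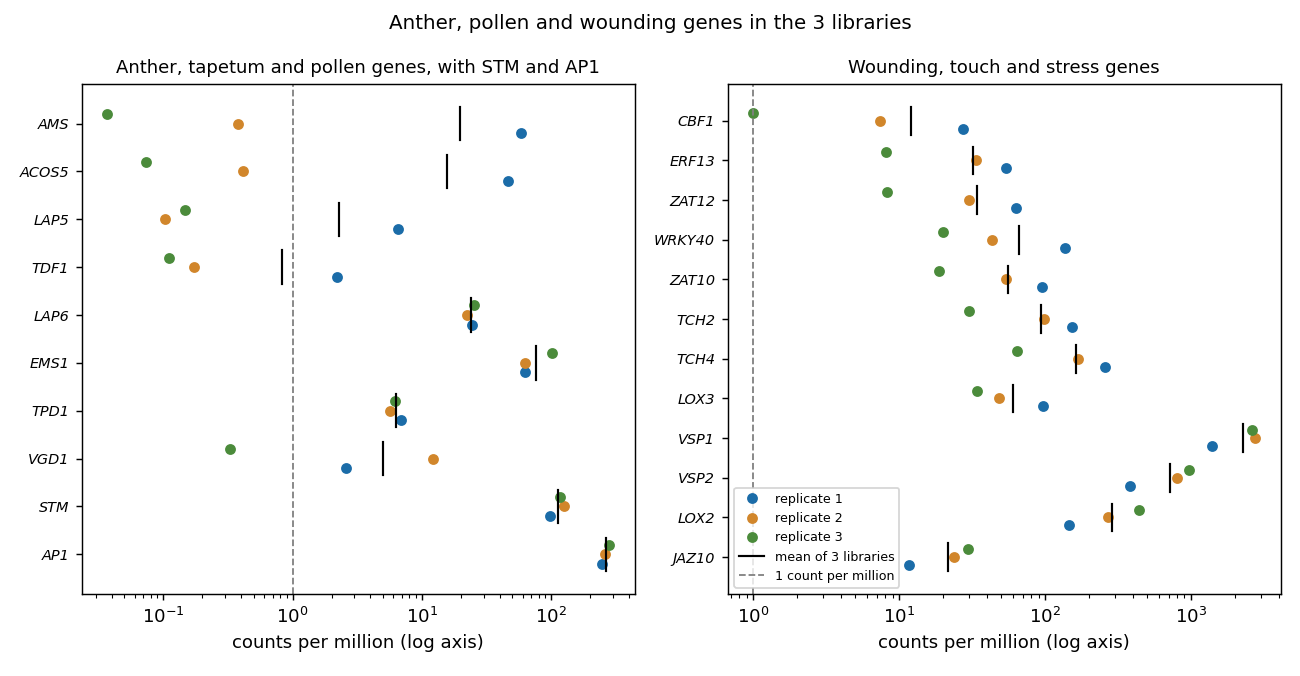
CPM (log axis) of 10 and 12 genes chosen after their values were seen, with 1 point per library, a black line at the mean of the 3 and a dashed line at 1 CPM. AMS and ACOS5 sit near 58.3 and 46.2 CPM in replicate 1 and below 1 CPM in the others, and CBF1 spans 0.991 to 27.4 CPM, while STM and AP1 did not vary more than the trend.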

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

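The test of genes listed at 0 in this part was chosen after the result was seen. The 4 values flagged here are signals in loci that no gene list, family or ratio used, each above the 1.1e-05% that a count of 0 allows. The 133 chloroplast loci took 0.0481 ± 0.00439% of all counts (SD, n = 3). The 146 mitochondrial loci took 0.00983 ± 0.00144%. Pseudogenes and transposable element genes, 3910 loci, took 0.202 ± 0.0118%, and the 487 nuclear loci that the reference lacks took 0.0258 ± 0.000909%. The nuclear loci count in the library sizes, and 122 pseudogenes or transposable element genes (1 varying) and 19 of the lacking loci (0 varying) were in the test of spread.

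Those 487 loci bear on genes that the counts list at 0. Of the 235 protein-coding genes whose number lies within 2 of such a locus, 37.4% (88 genes) were listed at 0 in all libraries, against 17.5% of the other 26465 genes (two-sided Fisher exact test, p = 4.3e-13). The 88 include, picked after their values were seen, GBF6, bZIP1, bZIP2, bZIP44, BZIP53, SAC51, TPPF, TPPG and LHW, and several of these are known to carry conserved upstream reading frames. A candidate explanation is that the authors' annotation held a separate locus on the same transcript, so that reads falling on both were left uncounted; 87 of the 91 lacking loci next to these genes were also at 0, but so were 444 of all 487. True silence of single genes stays open, no biological explanation was tested, and a listed 0 for LHW or the bZIP genes is weak evidence about expression.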

How the results depend on the processing

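The filter on the mean count and the mean level per gene were chosen after seeing the data, and the other alternatives were planned. The number of expressed genes ranged from 14665 (5 CPM) to 17911 (10 counts), and from 16942 to 17112 with 1 library left out. The means of 438 genes moved by less than 1 SD with TMM or DESeq2 scaling. Of 362 genes with a mean of at least 1 CPM, 18 moved by over 1.5 times without replicate 1, 2 without replicate 2 and 0 without replicate 3, and AMS fell to a mean of 0.209 CPM without replicate 1. TMM library sizes changed no call of a list or family. At 0.5 CPM, more lists passed, namely stem cell and meristem (95.7%), cytokinin signalling (88.5%), gibberellin (100%) and, below the others, anther and tapetum (33.3%). At 10 counts the same 4 lists passed with 95.7%, 88.5%, 100% and 33.3%, auxin transport passed with 100%, and the clock list missed with 100%. At 1 TPM-like the stem cell list passed with 91.3%. At 5 CPM, floral identity (80%), organ boundary (72.7%), the clock (80%) and pollen (0%) no longer passed, and Aux/IAA (44.8%), cytokinin metabolism (33.3%) and cellulose synthases (50%) moved below the other genes without passing. Families called higher fell to 5 at 5 CPM, where homeobox (61.5%), pentatricopeptide repeat (56.8%) and heat shock genes (62.7%) missed. Disease resistance genes passed below the others at 5 CPM (41.9%) and at 1 TPM-like (55.5%), and lay above them without passing at 0.5 CPM (67.0%) and 10 counts (67.5%). Without 1 library, the vascular list ranged from 60% to 70%, ovule and carpel from 57.1% to 71.4%, which changed their side of the other genes but no call, and pollen from 0% to 25%, which ended its call without replicate 3. Type-A over type-B ARR was -1.28 with no length correction and -0.96 as a mean level per gene, passing both times, AHK4 over AHK2 and AHK3 was -0.066 per gene and no longer passed, activating over repressing ARF genes was 0.44 per gene, with the sign reversed, PI and AP3 over AG (2.13), CUC1 and CUC2 over CUC3 (0.82) and YUC1 and YUC4 over the other YUC genes (4.83) passed per gene with sizes moved by at least 1 log2 unit, and STM over KNAT1 ranged from 0.20 to 0.48 without 1 library, passing without replicate 2. The biological coefficient of variation was 21.6% with no filter and 21.1% with the mean filter, and ranged from 16.6% to 17.5% without 1 library. The count of varying genes was 568 with no filter, 459 with DESeq2 size factors, 598 with a common dispersion, 572 with a DESeq2 trend, 562 with the mean filter, and from 216 to 289 without 1 library, where fewer samples leave less power. For the other changes the cause was not tested, except for some that follow by construction. A higher threshold leaves fewer genes expressed, and leaving out a library cannot lower their number. The mean level per gene shifts each ratio by a constant set by the numbers of genes on its sides. Depth limits genes near 1 CPM, such as CLV3, HEC2 and PUCHI, whose calls rest on about 29.1 counts in replicate 1. No paired analysis was possible because the series has 1 group.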

Other observations

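In this part, the tests of meristem genes, of scaling and of older buds as a source of the touch and wound signal were chosen after the result was seen; the tests on further gene lists were written before those genes were looked at.

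Genes of the low-sugar response, picked because AT3G15450 and SIP2 were lower in replicate 2, were expressed in all libraries. No p-value was computed for the list, and a lower level in replicate 2 does not mean that each member varied more than the trend. The asparagine synthetase gene ASN1 had 1110, 543 and 1517 TMM-scaled CPM in replicates 1, 2 and 3, SEN1 had 539, 185 and 538, and DRM1 had 1076, 646 and 858. All 12 members of the list were lower in replicate 2 than in the mean of the others, with a median log2 ratio of -0.92 and a range from -1.54 to -0.33. As a hypothesis, the sugar or light dependent state of the replicate 2 pool may have differed, and the labels give nothing to test it against.

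Several tapetum genes were high in replicate 1 alone, where 53 genes held 0.151% of nuclear counts, among them, picked after their values were seen, AT1G27710 (6706, 56 and 7 counts), AT5G62080 (4989, 49 and 3 counts) and the tapetum gene ATA1 (177, 3 and 0 counts). A library of older flowers as a whole is argued against by the stem cell and meristem genes, whose median log2 ratio of replicate 1 to the others was -0.18 over 20 genes, and library scaling by a TMM factor ratio of 1.0. Some older bud tissue left in the replicate 1 pool, which the removal of buds was meant to take out, is a candidate explanation that its test left open: over a further list of tapetum, exine and meiosis genes the median log2 ratio to the higher of the other libraries was 0.77, between the bounds set beforehand, and 7 of its 12 genes were expressed in all libraries. MMD1 (131, 3 and 1 counts), CALS5 (468, 92 and 91 counts), TKPR1, TKPR2 and ASY1 exceeded a log2 ratio of 1, the other 5 of 10 genes with more than 3 counts, among them DMC1, SDS and QRT3, did not, and LTP12 and MS2 had 0 counts in replicate 1. Apart from older tissue in the pool, no biological explanation was tested, since the design has 1 group. In the median of the 53 genes replicate 2 held 0.943% and replicate 3 held 0.226% of the replicate 1 level.

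Of the 15 varying touch, wound and stress genes, 12 were highest in replicate 1, such as WRKY40 (136, 43.1 and 19.8 CPM) and ZAT12 (63.4, 29.9 and 8.26 CPM), both picked after their values were seen, while VSP2, LOX2 and JAZ10 were lowest there. Library scaling is argued against by a TMM factor ratio of 1.03 between replicates 1 and 3. If older bud tissue in replicate 1 were the whole source, these 12 genes should be alike in replicates 2 and 3, both low in AMS and ACOS5. Their median log2 ratio of replicate 2 to replicate 3 was 1.40, from 0.11 to 2.72. That order was already seen when the test was chosen. The 53 genes high in replicate 1 stood in replicates 2 and 3 at medians of only 0.943% and 0.226% of the replicate 1 level. Bud tissue in such amounts would leave the 12 genes about alike in replicates 2 and 3. These values therefore argue against older bud tissue, as marked by the 53 genes, as the whole source for the 12 genes. Whether it gave part of their excess in replicate 1 stays open. Over 15 further early-response genes, listed because of this pattern but not looked at before, the median log2 ratio of replicate 2 to replicate 3 was only 0.64, with 10 of 15 above 0. Unequal handling of the pools before freezing may account for the 12 genes: over the same 15 further genes the median log2 ratio of replicate 1 to replicate 3 was 1.92, with 14 of 15 above 0 and SZF1 at 526, 217 and 57.2 TMM-scaled CPM, though 5 of them were lowest in replicate 2. Any other cause that raises early-response genes in replicate 1 would give such a value too, so it does not single out handling. Time of day stays open, since 2 of 10 clock genes varied when adjusted over that list alone, and apart from older bud tissue no biological explanation was tested.

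Pollen genes formed a separate, fainter signal in replicate 2. Over 11 of 12 further mature pollen genes with more than 3 counts, the median log2 ratio of replicate 2 to the higher of the other libraries was 1.95, and 11 of 11 were above 0. These ratios rest on few counts. Several of the genes also stood higher in replicate 1 than in replicate 3, as AGP11 (17, 71 and 4 counts) and PRK2 (7, 38 and 0 counts). Others, as ACT4 (0, 13 and 0 counts) and CPK34 (1, 3 and 1 counts), did not. These 4 were picked after their values were seen. As a hypothesis, a few pollen grains may have reached the replicate 2 pool; the most abundant of these genes, AGP6, had 2.82 TMM-scaled CPM there and 0.653 and 0.338 in replicates 1 and 3, and 0 of the 12 were expressed in all libraries.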
